A study of Homo sapiens with 20 samples.

How the data were processed

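RNA from separated epidermis of donors with EBS was sequenced, and a gene table was deposited for each of the 20 libraries. Per the submitters' processing notes the tools were HISAT, Bowtie2 and RSEM and the genome build was hg38, and the versions and settings are not given in the sources used here. Per the file headers, the deposited values are expected counts, RSEM's estimates of reads per gene, which need not be whole, and FPKM values. The FPKM values deposited by the authors were not used for tests. Between 78.5% and 85.6% of the listed expected counts in a library were exactly whole. Each table lists the genes with a count above 0, so a gene absent from a table was taken as 0.

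The tables came in 2 layouts, with 5 columns in 10 files and 12 columns in 10 files. The first layout held 4 blister and 6 nonblister libraries and the second 5 and 5. The transcript lists showed that 2 RefSeq transcript sets had been used, the larger in 16 libraries and the other in 4 (2 blister, 2 nonblister), and 23.5% of shared genes had different transcripts in the sets. Of 21923 genes listed, 21830 matched a symbol in the RefSeq gene table (GRCh38.p14, whose primary assembly is that of hg38). Genes listed under both sets were kept, 17262 in all, which hold 97.30% to 99.97% of the counts of a library. Sex-linked genes (44, the Y-linked genes with XIST and TSIX) were left out of every step, because the samples are from people. Mitochondrially encoded transcripts are not listed in the tables.

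Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr (14069 kept, 3193 filtered out), libraries were scaled by TMM, and blister was compared with nonblister by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. A list score is the mean log2 CPM of its members, with a prior count of 2. TMM factors were 0.411 to 0.912 (median 0.76) in blister and 1.126 to 1.425 (median 1.28) in nonblister libraries. Depth limits the values of genes near 0 counts, and the counting interval of DEFB4A covers counting error only.

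The 42 lists were fixed in advance, and 39 had at least 3 tested members, and the counts given for a list are of its tested members. The filter keeps a gene nearly absent from nonblister libraries only if the blister libraries express it. Such a member could be tested only where it was higher in blister epidermis. Counts of risen members, list medians and list tests therefore do not describe the whole fixed list. Markers of Merkel cells and of B and plasma cells had too few tested members, as did the mitochondrially encoded transcripts. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. With the preset correlation 26 lists passed, 19 upward and 7 downward, and with an estimated one 5 passed. The genes named are the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 10 CPM in the higher group and the same direction in at least 8 of 9 donor pairs, the fixed genes KRT5, KRT14, PLEC, KRT6A, KRT16, KRT17, MTOR, RPS6 and EIF4EBP1, and from each list up to 4 members with the smallest adjusted p and up to 2 with the highest mean CPM. Not every gene that the rule takes is reported here.

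The numbers in the labels pair the libraries of 9 donors, because the protocol takes both biopsies from the same patients. Deviations from the group means correlated at -0.071 to 0.337 between libraries of 1 donor (median 0.116, over 0.1 in 5 of 9 pairs), against a median of -0.007 for other pairs. The main fit has no donor term, and the paired fit with the donor as a replicate block is an alternative. No 2 libraries agreed within sampling noise (smallest chi-square per degree of freedom 172.704 among blister and 43.29 among nonblister libraries).

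The alternatives fixed before the data were examined were the replicate block, the file layout as a covariate or each layout alone, the 18 libraries of donors with both sites, DESeq2 1.42.0, limma-voom with quality weights, upper-quartile or library-size scaling, no filter or a strict filter (5 CPM in at least 9 libraries), and each library left out in turn. The transcript set as a covariate, the larger set alone, the omission of 2 particular libraries and the counting of coding genes of 1 set as 0 were chosen after seeing the data. On simulated counts for 13983 genes, 200 of them changed, edgeR recovered 50% of genes changed 2-fold, 90% at 4-fold, 90% at 8-fold and 98% at 16-fold, and 3% of its calls were unchanged genes. DESeq2 recovered 58%, 94%, 100% and 100%, with 14.6% of its calls unchanged, and limma-voom 42%, 84%, 86% and 96%, with 2.5%. Both changed lists were found and none of 20 unchanged lists. Simulated genes were drawn independently of each other, while the real lists had estimated correlations of up to 0.93. The simulation therefore cannot show how often the preset correlation passes unchanged lists in these data. Its 200 changed genes, raised and lowered in equal number, were also far fewer than the 7979 called in the data. The shares of unchanged calls need not carry over. Correlations and bootstrap intervals were computed with Python 3.11.15 and scipy 1.17.1, and figures with matplotlib 3.10.9.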

Results

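Epidermolysis bullosa simplex (EBS) is an inherited skin fragility disease, most often of the basal keratins, in which minor friction splits the epidermis and raises blisters. RNA was sequenced from the epidermis of 4 mm punch biopsies of 11 donors with EBS. A blister biopsy, taken within 1 week of blister onset, was available from 9 donors, and a biopsy of skin without blistering from all 11, giving 9 blister and 11 nonblister libraries. The total expected count per library, in units of 1e6, ranged from 17.11 to 25.44 with a median of 23.04. It averaged 24.33 ± 1.20 (SD, n = 9) in blister and 21.90 ± 1.91 (SD, n = 11) in nonblister libraries. The series title names a search for drugs to reposition and an mTOR inhibitor, and its design has a single contrast, blister against nonblister epidermis.

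Blister epidermis had far more transcript of the wound keratins, the antimicrobial proteins and the IL-17 and IL-36 response genes. It also had more transcript of the glycolytic enzymes and less of dermal, melanocyte and Langerhans cell markers, and these list calls were lost with an estimated correlation (adjusted p = 0.05953 for glycolysis, 0.1968 to 0.3112 for dermal lists, 0.1874 and 0.5191 for the others). Of 14069 genes tested, 7979 (56.7%) changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). They were 4439 genes higher and 3540 lower in blister epidermis, and 5423 changed at least 2-fold, 3005 of them upward and 2418 downward. With the donor as a replicate block in the 9 pairs, 2861 genes were higher and 3176 lower. Within the first file layout (4 blister and 6 nonblister libraries) 6065 genes changed, and within the second (5 and 5) 4753 did. The split between higher and lower genes moved with the scaling: 55.6% of changed genes were higher with TMM, 36.0% with upper-quartile factors and 19.7% with library size alone, and the median log2 fold change of all genes was 0.07, -0.30 and -0.73 in turn. Every blister sample separated by itself and every nonblister sample was separated by a freeze-thaw cycle, so blister status and separation method cannot be told apart.

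The keratins that keratinocytes induce after wounding rose together. KRT6A (chromosome 12, 52487176 to 52493257, hg38) went from 218 ± 127 CPM in nonblister to 36410 ± 19250 CPM in blister epidermis (SD, n = 11 and 9), a log2 fold change of 7.38 ± 0.52 (SE, adjusted p = 3.31e-09). KRT16 rose by a log2 fold change of 7.49 ± 0.54 and KRT17 by 6.42 ± 0.55, each in 9 of 9 donor pairs. All 5 members of the list rose, and the list test gave an adjusted p of 1.257e-12 (camera, preset correlation 0.01). Over the 39 lists tested, 26 passed with this preset correlation, as many as in 10 of 100 splits of the libraries, and 5 passed with an estimated correlation. These keratins have close paralogs and pseudogenes, so the division of reads among them is uncertain. The basal keratins that are mutated in EBS did not pass the test. KRT14 had 25920 ± 19170 CPM in blister and 13380 ± 3707 CPM in nonblister epidermis (log2 fold change 0.96 ± 0.41, adjusted p = 0.05135), and it passed, among other settings, with DESeq2, with limma-voom and without the blister library of lowest TMM factor (adjusted p = 0.03114, 0.006641 and 0.01009). KRT5 stood at 0.08 ± 0.48 and PLEC, which encodes the linker protein plectin, at 0.01 ± 0.22, and both values turned negative under upper-quartile and library-size scaling.

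**Figure D1:**
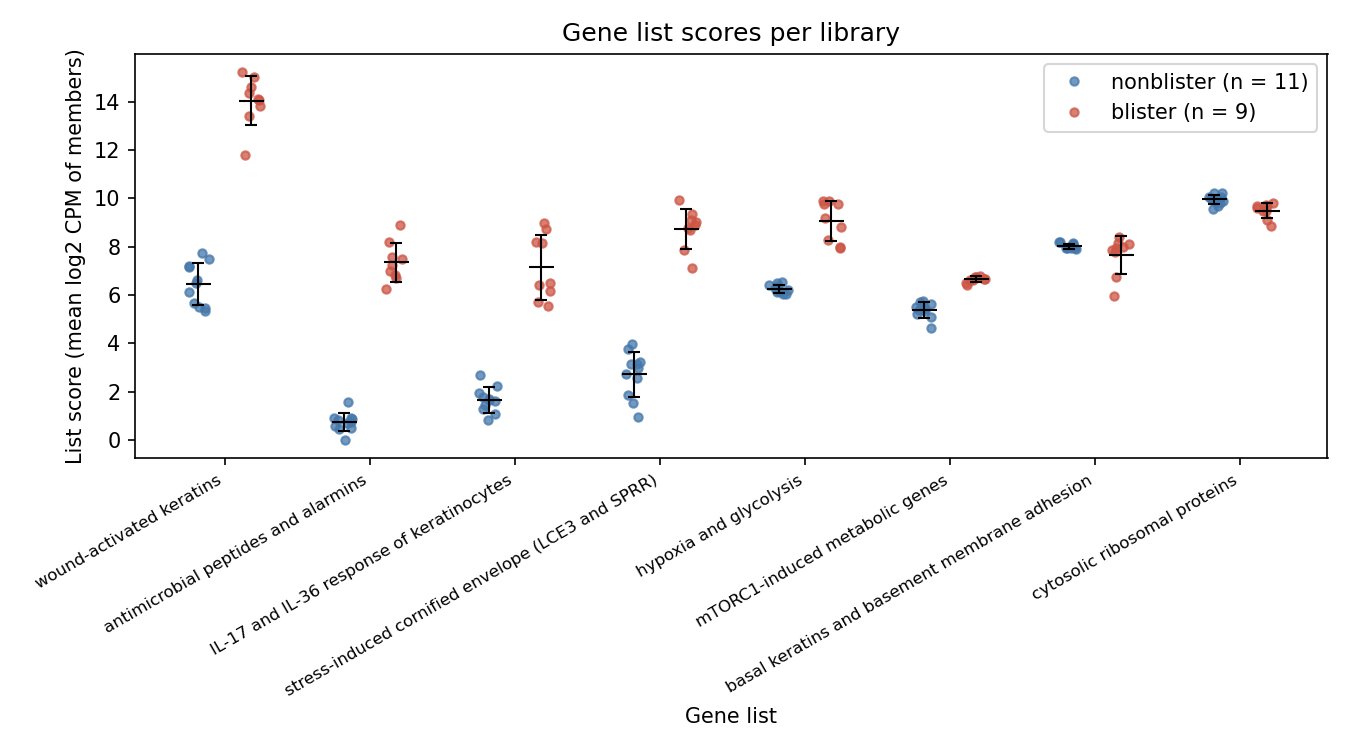
Mean log2 CPM of the members of 8 gene lists (y axis) in each of 11 nonblister and 9 blister libraries (points), with group mean and SD (black bars). The wound keratin score averaged 14.04 in blister and 6.44 in nonblister libraries, while the basal keratin and adhesion scores averaged 7.66 and 8.02.

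Genes of basement membrane adhesion moved both ways. Of 20 members of the basal keratin and adhesion list 6 rose and 5 fell (7 and 5 adjusted over the list alone), with a median log2 fold change of 0.12, a mean of -0.001 and no shift of the list (adjusted p = 0.959). LAMB3, a chain of laminin-332, rose by 2.23 ± 0.39 and the cadherin CDH3 by 2.41 ± 0.29. COL7A1, the anchoring fibril collagen, had a log2 fold change of -2.69 ± 0.45. Desmosome and adherens junction genes rose in 9 of 15 cases, among them DSC2 (5.43 ± 0.38) and DSG3 (3.57 ± 0.34), and the list test passed (adjusted p = 0.003834) but not with an estimated correlation (adjusted p = 0.4349).

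Antimicrobial and alarmin genes had the highest list median over tested members, a log2 fold change of 8.17. Of 13 tested members, of 16 fixed, 12 were higher. S100A9 and S100A8, which form calprotectin, rose by 9.68 ± 0.44 and 8.88 ± 0.47, and the elastase inhibitor PI3 by 9.20 ± 0.38. DEFB4A had 7379 counts in the blister libraries and 2 in the nonblister libraries, which is a ratio of 7003 (95% counting interval 1938 to 57830) relative to the TMM-scaled library sizes summed over each group. Its fitted fold change, 3727, depends on the prior count, and its reads may be shared with an identical copy. All 11 tested members of the IL-17 and IL-36 response, of 20 fixed, rose, including SERPINB4 (9.27 ± 0.71) and IL36G (3.60 ± 0.38). All 12 tested members of the list of LCE3 and SPRR genes, stress-induced proteins of the cornified envelope, which also holds involucrin (IVL), rose as well, including SPRR2A (9.89 ± 0.73), SPRR1B (5.81 ± 0.52) and IVL (3.91 ± 0.49). These 3 lists and the wound keratins passed with an estimated correlation too, at adjusted p of 0.003189, 0.003189, 0.0207 and 0.01622 in turn. Counts adjusted over the list alone were the same here and elsewhere unless given. The neutrophil and monocyte markers described below were higher in the blister group too.

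The highest fold changes belonged to inflammatory genes and rested partly on 1 blister library, the one with the lowest TMM factor (0.411). The 10 highest among genes that met the naming rule (at least 10 CPM in the higher group, 8 of 9 donor pairs) were CXCL8, CCL3L1, CCL3, IL1B, OSM, CXCL1, CXCL5, TREM1, LILRA3 and DEFB4A. CXCL8, which encodes the neutrophil attractant interleukin-8, had a median of 469.4 CPM in blister libraries, a range of 5.6 to 140200 CPM, and a nonblister median of 0.3052 CPM. Its log2 fold change was 13.21 ± 2.15, and 10.34 ± 1.64 without that library. The same omission took CCL3L1 from 12.78 to 8.25, CCL3 from 12.70 to 7.91, IL1B from 12.69 to 9.09, OSM from 12.58 to 7.04, CXCL1 from 12.38 to 10.72, TREM1 from 12.16 to 10.36 and LILRA3 from 12.04 to 7.84, all still past the threshold. CXCL5 had 12.24 with it and 12.27 without it. CCL3 and CCL3L1 are near-identical copies, so their separate values are uncertain.

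Targets of inflammatory signalling also rose, in libraries whose neutrophil and monocyte markers were higher too (median log2 fold changes 5.78 and 5.03). All 18 NF-kB targets were higher, with TNFAIP3 at 5.26 ± 0.70 and SOD2 at 7.45 ± 1.29, or 3.80 and 4.37 without the library of lowest TMM factor. So were all 23 tested interferon-response genes, with OASL at 8.12 ± 0.76 and ISG15 at 7.95 ± 1.17 (7.42 and 5.66 without that library), and 13 of 17 tested genes of the IL-6 and STAT3 list, with IL4R at 3.34 ± 0.35. SOCS3 had 8.07 ± 1.27, and 4.20 ± 0.48 without it. Of 18 tested migration and matrix remodelling genes 15 rose (15 higher and 1 lower adjusted over the list alone), including the collagenase MMP1 (9.72 ± 0.82), the urokinase receptor PLAUR (8.93 ± 1.14) and the growth factor HBEGF (6.69 ± 0.63). Without that library they had 9.12, 6.49 and 5.83. The lists of NF-kB, interferon, IL-6 and migration genes passed with the preset correlation but not with an estimated one, at adjusted p of 0.5134, 0.5178, 0.309 and 0.1785 in turn.

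Glycolytic transcripts and most of the metabolic genes that mTORC1 is known to induce were higher in blister epidermis. All 20 hypoxia and glycolysis genes rose, with a median log2 fold change of 2.78, and the list test gave an adjusted p of 1.718e-16, or 0.05953 with an estimated correlation. HK2, a hexokinase, which phosphorylates glucose, rose by 5.24 ± 0.40, LDHA by 2.50 ± 0.21, GAPDH by 2.14 ± 0.24 and the glucose transporter SLC2A1 by 2.31 ± 0.37. Of 25 mTORC1-induced genes, 18 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 1.93. This list passed with both correlations (adjusted p = 3.89e-06 preset and 0.008162 estimated). Its score averaged 6.65 ± 0.12 in blister and 5.38 ± 0.32 in nonblister libraries (SD, n = 9 and 11), and it was higher in 9 of 9 donor pairs.

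Among the components of the mTOR and PI3K-AKT pathway, 12 of 27 rose and 5 fell. EIF4EBP1, the translation repressor that mTORC1 phosphorylates, rose by 2.77 ± 0.21 (adjusted p = 7.267e-09). The stress-induced mTORC1 inhibitors SESN2 and DDIT4 rose by 3.66 ± 0.34 and 5.35 ± 0.59 (DDIT4 by 4.21 ± 0.31 without the blister library of lowest TMM factor), while SESN1 had a log2 fold change of -1.42 ± 0.25. MTOR itself did not pass, at 0.12 ± 0.19 (adjusted p = 0.6208). With library size alone it was lower, at -0.65, where the median of all genes was -0.73. The list median was 0.34, and the list test passed with the preset correlation (adjusted p = 0.03525) but not with an estimated one (adjusted p = 0.1195) or with library size alone (adjusted p = 0.07862). Ribosomal protein genes were lower: 16 of 30 fell and none rose, with a median of -0.40. RPS6 stood at -0.65 ± 0.19 (adjusted p = 0.005973) and RPL13 at -0.76 ± 0.15. RPS6 did not pass within either file layout alone (adjusted p = 0.1348 and 0.06442), nor RPL13 within the second (adjusted p = 0.06788). The list test gave an adjusted p of 0.003834, or 0.6312 with an estimated correlation, and processed pseudogenes may share reads with these genes.

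**Figure D2:**
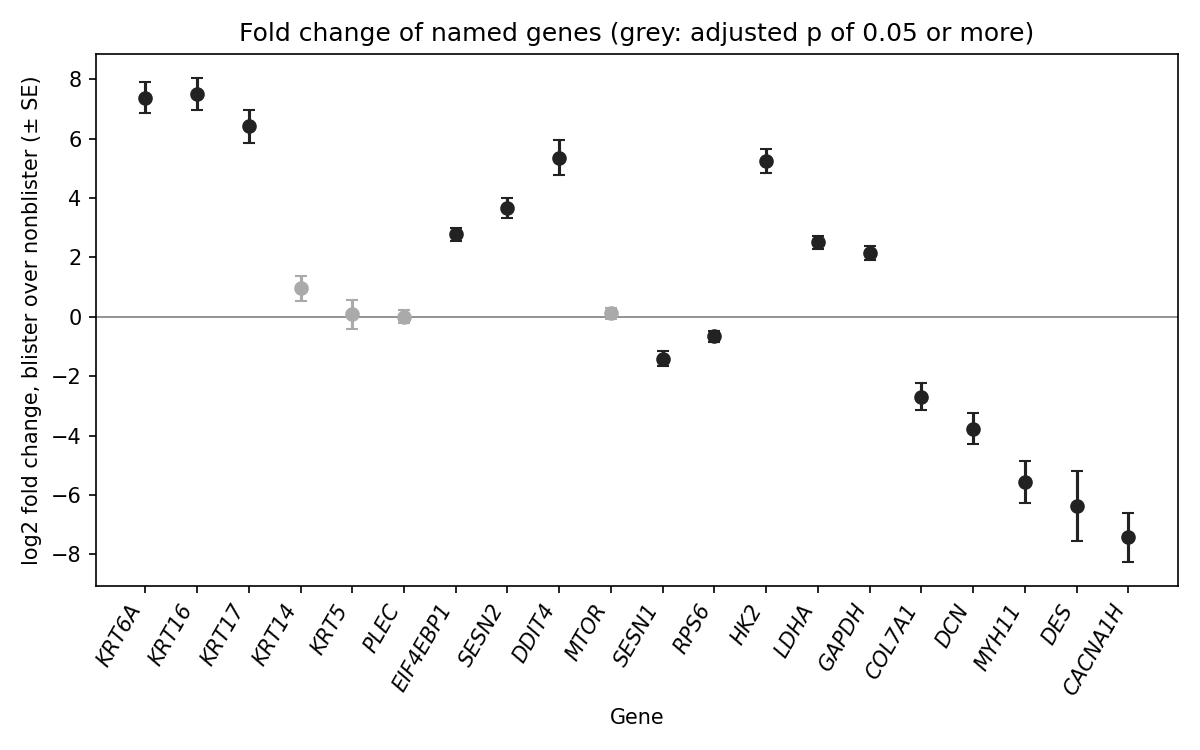
Log2 fold change of blister over nonblister epidermis (y axis) for 20 genes, with the SE of the edgeR fit as bars and grey points for genes with an adjusted p of 0.05 or more. KRT6A stands at 7.38 and CACNA1H at -7.43, while KRT5, PLEC and MTOR lie near 0, and these last genes turn negative under upper-quartile and library-size scaling.

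Neutrophil and monocyte markers were higher in blister epidermis and varied widely between its libraries. All 8 tested neutrophil markers, of 13 fixed, rose, including FPR1 (11.05 ± 1.38) and CSF3R (10.04 ± 1.44), and so did all 14 tested monocyte and macrophage markers, of 16 fixed, including CD68 (7.20 ± 0.71) and CD14 (7.82 ± 1.22). Without the library of lowest TMM factor these stood at 10.13, 8.11, 6.32 and 6.42. The list tests gave adjusted p of 0.0002596 and 0.002884, and 0.309 and 0.5181 with an estimated correlation. The mean of both scores was 4.65 ± 2.53 in blister and 0.44 ± 0.64 in nonblister libraries (SD, n = 9 and 11). All 9 tested T cell markers rose, with IL7R at 6.91 ± 0.95 (6.10 without that library), and so did 4 of 5 tested cytotoxic lymphocyte markers, but neither list test passed (adjusted p = 0.1172 and 0.3283). With library size alone both did (adjusted p = 0.003549 and 0.02667), and the T cell list also did with upper-quartile scaling (adjusted p = 0.02821). GZMB, the cytotoxic protease, had 9.53 ± 1.63, and 5.12 ± 0.86 without the library of lowest TMM factor.

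**Figure D3:**
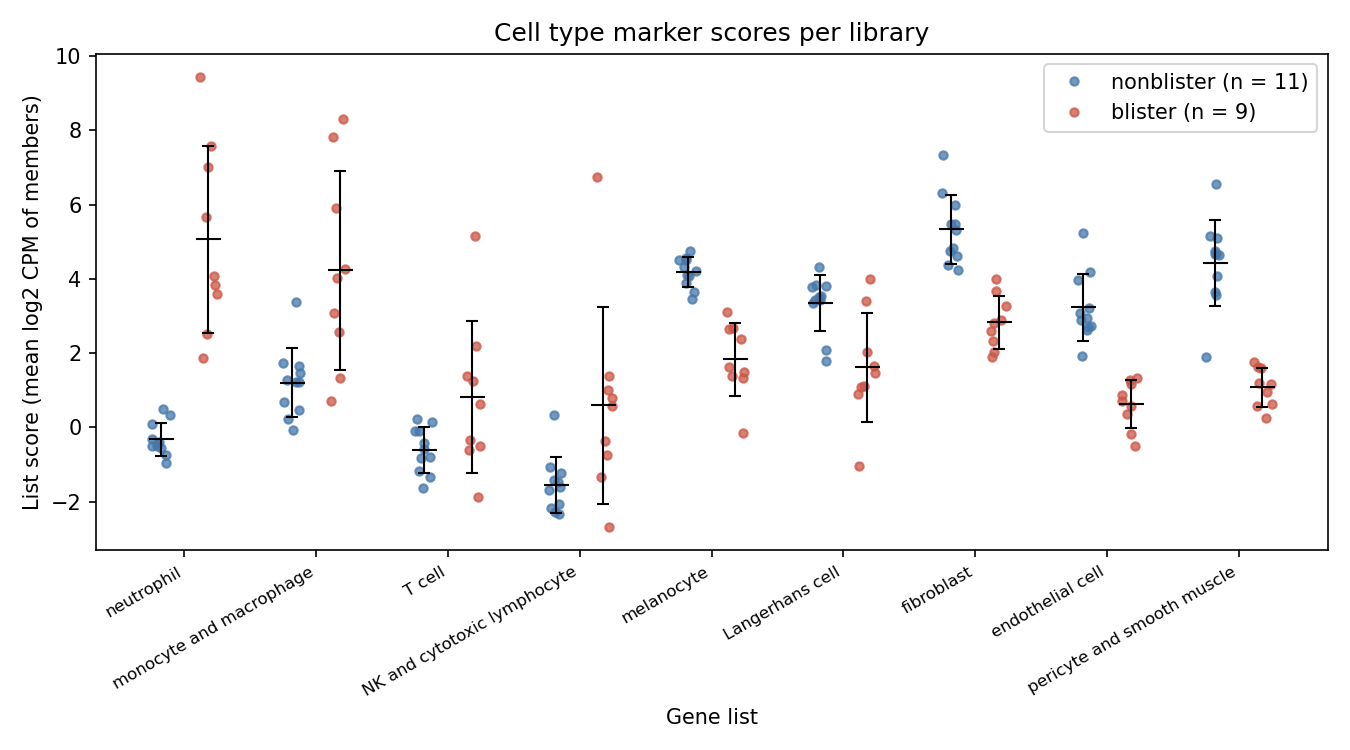
Mean log2 CPM of the markers of 9 cell types (y axis) in each of 11 nonblister and 9 blister libraries (points), with group mean and SD (black bars). The fibroblast score averaged 2.83 in blister and 5.34 in nonblister libraries, and the neutrophil score 5.07 and -0.31.

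Dermal markers were lower in blister epidermis and supplied several of the lowest fold changes. Of 15 fibroblast markers 12 fell, of 12 endothelial markers 8, and of 10 pericyte and smooth muscle markers 8, with medians of -2.87, -3.14 and -4.07. DCN, a small proteoglycan of the dermis, stood at -3.77 ± 0.53, COL1A1 at -1.98 ± 0.47 (adjusted p = 0.06276 within the first layout) and the endothelial gene PLVAP at -3.70 ± 0.58. The 3 lists passed with the preset correlation but not with an estimated one (adjusted p = 0.3112, 0.3112 and 0.1968), though in the paired fit (replicate block) the smooth muscle list passed with an estimated correlation too (adjusted p = 0.03169). The 10 lowest fold changes were CACNA1H (-7.43 ± 0.83), DES, MYH11, POSTN, SFRP2, PI16, KRT27, CNN1, ATP6V1B1 and PAMR1 (-5.02 ± 0.40), which include smooth muscle genes (DES, MYH11, CNN1) and the hair follicle keratin KRT27. With limma-voom, CACNA1H, DES, KRT27 and CNN1 did not pass (adjusted p = 0.06273, 0.1963, 0.268 and 0.07358), and DES stood at -6.38 ± 1.17, or -7.59 ± 1.18 without the blister library of lowest TMM factor and -5.55 ± 1.04 without the nonblister library of lowest count. PI16 stood at -5.31 ± 1.06, or -5.95 ± 1.11 without the former. In nonblister libraries PI16 had a mean of 11.97 CPM, a median of 3.783 CPM and a highest value of 93.77 CPM. KRT27 had a mean of 10.56 CPM there, a median of 0.5355 CPM and a highest value of 58.9 CPM. Both reached the 10 CPM of the naming rule only through their highest nonblister libraries.

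Resident epidermal cell markers fell too. Of 13 melanocyte markers 12 fell, including DCT (-3.12 ± 0.48) and PMEL (-1.49 ± 0.38), and the list passed (adjusted p = 7.827e-07, or 0.1874 with an estimated correlation). Of 8 Langerhans cell markers 5 fell, with CD207, which encodes langerin, at -1.95 ± 0.50, and the list test gave 0.03849, or an adjusted p of 0.5191 with an estimated correlation. It did not pass under upper-quartile or library-size scaling (adjusted p = 0.1069 and 0.2868) or without the blister library of lowest TMM factor (adjusted p = 0.06317), and CD207 did not pass within the first layout (adjusted p = 0.1251). Of 31 late differentiation genes 5 rose and 4 fell (5 and 1 adjusted over the list alone), without a shift of the list (adjusted p = 0.1665). KRT10, a suprabasal keratin, stood at -1.58 ± 0.57, which did not pass within either layout alone (adjusted p = 0.127 and 0.1277), and KRT77 at -3.97 ± 0.60. The protease KLK5 rose by 1.68 ± 0.45, which did not pass with the replicate block, within the second layout or with library size alone (adjusted p = 0.1026, 0.2075 and 0.06479).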

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

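For all splits of the libraries and exchanges within donors, the expected outcomes were set down after their results were known. The splits with an estimated correlation, the further splits, the exchanges and the test of genes of 1 transcript set were also chosen after seeing the data.

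Among 125 values compared within the 9 blister libraries (library measures, list scores and log2 CPM of named genes), 11 had an extreme library whose gap to its nearest neighbour, as a share of the group's range, exceeded Dixon's 95% critical value. Chance gives about 1 in 20 such values, and all 11 came from the same blister library. The 11 are not independent, because DSG3 and GZMB belong to lists whose scores are among them. The TMM factor, which scales the other values, is among them too. The TMM factor of this library was 0.411, against 0.705 to 0.912 in the other blister libraries. Its cytotoxic lymphocyte score was 6.75 (others -2.68 to 1.38) and its desmosome and adherens junction score 6.66 (others 8.97 to 10). On the log2 CPM scale it was highest for SOCS3 (14.3, others 5.54 to 8.63), DDIT4 (13, others 8.18 to 10.6), GZMB (8.92, others -1.97 to 3.19) and DES (1.72, others -3.56 to -0.95). It was lowest for IVL (7.44, others 9.73 to 12), KLK5 (5.86, others 9.55 to 12), DSG3 (6.95, others 9.11 to 11.2) and PAMR1 (-3.56, others -0.579 to 1.13). Without this library 8307 genes changed, 4290 higher and 4017 lower. The nonblister group of 11 was not compared in this way.

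Genes listed under the larger transcript set alone, mostly noncoding, were outside the comparison. In its 16 libraries 1046 of them could be tested, 15 of them coding, and 555 changed, 111 higher and 444 lower in blister epidermis (edgeR quasi-likelihood test, adjusted p under 0.05). Genes with the smallest adjusted p, named after their values were seen, were LINC00707 (log2 fold change 8.01 ± 0.48, adjusted p = 4.79e-09) and the keratin pseudogene KRT16P3 (5.66 ± 0.45), whose reads may be shared with KRT16, a doubt that the value of 111 does not settle.

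Chance was weighed with 100 splits of the 20 libraries into 9 and 11, the real split included, which ignore the pairing by donor. Only the real split, 1 of 100, gave as many changed genes (7979, highest other 0), and likewise for genes changed at least 2-fold (5423, highest other 0). Chance is therefore an unlikely source of both counts, though 1 of 100 is the smallest share that 100 splits can give. At an unadjusted p under 0.05 the real split had 8674 genes and the highest other 3610. The 0 depends on the draw: of 24 further splits, drawn to check it, 1 called 680 genes, 676 of them changed at least 2-fold. For the lists, 10 of 100 splits passed at least the 26 lists of the real split with the preset correlation (highest other 32, median of the others 17), so chance cannot be excluded for that count. With an estimated correlation 1 of 100 splits, the real one, reached 5 lists (highest other 1), and chance is an unlikely source of that count. Exchanging blister and nonblister within the 9 donor pairs keeps the pairing, and 40 such assignments, the real one included, were fitted with the donor as a block. Again 1 of 40, the real one, gave as many changed genes (6037, highest other 2), genes changed at least 2-fold (4507, highest other 2) and lists with an estimated correlation (6, highest other 0). Chance is an unlikely source of these, though 1 of 40 is the smallest share that 40 assignments can give. At an unadjusted p under 0.05 the real assignment had 7259 genes and the highest other 4230. With the preset correlation 8 of 40 reached the 26 lists of the real one (highest other 27), so chance cannot be excluded for that count.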

How the results depend on the processing

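The fits by transcript set and without particular libraries were chosen after seeing the data. Leaving out each library in turn gave 7599 to 8307 changed genes, 5174 to 5736 changed at least 2-fold, 4220 to 4499 higher and 3351 to 4017 lower. With the paired fit (replicate block), 2861 genes were higher, and of its 6037 changed genes 5847 were shared with the unpaired fit, all in the same direction. In the paired fit the lists of barrier lipids and Schwann cells no longer passed, those of mast cells and eccrine glands did, KLK5 was lost, and no other call of a named gene, or of a list at the preset correlation, changed side. With an estimated correlation the smooth muscle list passed in the paired fit (adjusted p = 0.03169), besides the 5 lists of the unpaired fit. The second layout alone, with 10 libraries, gave 4753 changed genes, 2787 higher and 1966 lower. Upper-quartile scaling gave 5316 lower genes, library size alone 1861 higher and 7565 lower, and the strict filter, which tests fewer genes, 3449 changed at least 2-fold. An estimated correlation left 5 lists.

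Values near 0 changed sign. With upper-quartile scaling and library size alone the median log2 fold change of all genes moved down as well, to -0.3 and -0.73. For the other settings the cause was not tested. KRT5 had a log2 fold change of -0.547 with the replicate block, -0.208 in the second layout, -0.193 with upper-quartile scaling, -0.588 with library size alone, -0.052 with the strict filter, -0.079 with limma-voom and -0.117 with the transcript set as covariate. PLEC had -0.033 with the block, -0.448 in the first layout, -0.017 in the unpaired fit of donors with both sites and with DESeq2, -0.39 with upper-quartile scaling, -0.793 with library size alone, -0.007 without a filter, -0.124 with the strict filter, -0.032 with limma-voom and -0.169 in the larger transcript set. MTOR had -0.028 with the block, -0.038 in the second layout, -0.222 with upper-quartile scaling, -0.647 with library size alone and -0.014 with the strict filter. PLEC and MTOR passed as lower with library size alone, where both lay near the median of all genes (-0.73).

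Some list tests that did not pass turned in the direction that camera assigns. The values in parentheses are a different measure, the list median minus the median of all genes, and most kept the sign of the main fit. The tests that turned were the basal list with the block (0.058), and the cell cycle list with layout as covariate (0.242), upper-quartile scaling (0.411), library size alone (0.448), the larger transcript set (0.668) and without the library of lowest TMM factor (0.502). Oxidative phosphorylation (0.009 and -0.007) and sebaceous gland (-2.036 and -1.988) did so with upper-quartile scaling and library size, late differentiation with library size (-0.556), sebaceous gland in the larger transcript set (-0.547) and adipocyte without the library of lowest TMM factor (-0.239). Over 82 named genes and their alternatives, 1242 of 1289 values kept direction and side of the threshold, 19 lost and 6 gained a call, and 22 reversed.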

Other observations

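The test of dilution was chosen after its values were seen. Stress-response genes were higher in blister epidermis, where neutrophil and monocyte markers were higher too. Of 15 unfolded protein response genes 14 rose, with the chaperone HSPA5 at a log2 fold change of 2.31 ± 0.26 (SE), and of 12 heat shock genes 10 rose, with HSPA6 at 5.48 ± 0.78. Of 15 immediate early genes 11 rose (14 adjusted over the list alone), with JUN at 3.77 ± 0.57 (3.05 without the library of lowest TMM factor). The 3 lists passed with the preset correlation (adjusted p = 2.361e-06, 0.0003587 and 0.002033) but not with an estimated correlation (adjusted p = 0.1785, 0.1226 and 0.4331). Of 14 p53 targets 6 rose and 1 fell, with the cell cycle inhibitor CDKN1A at 3.63 ± 0.32 (list adjusted p = 0.03194, 0.2075 with an estimated correlation and 0.05516 in the larger transcript set alone). Barrier lipid genes rose in 14 of 24 cases and fell in 1, with the ceramide glucosyltransferase UGCG at 2.85 ± 0.36, and the list passed (adjusted p = 0.01369) but not with an estimated correlation (adjusted p = 0.6312) or in the paired fit (adjusted p = 0.05941).

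Among the remaining lists, only that of Schwann cells passed in the unpaired fit. Cell cycle genes rose in 6 of 25 cases (2 adjusted over the list alone), with a positive median of 0.40 and a test leaning down (adjusted p = 0.9781). Cholesterol synthesis had 4 higher and 1 lower of 17 (3 and 1 adjusted over the list alone, adjusted p = 0.4234, or 0.02498 in the larger transcript set alone), and nuclear oxidative phosphorylation 3 and 1 of 20 (adjusted p = 0.71). Schwann cell and nerve markers fell in 4 of 6 cases, at a list adjusted p of 0.04747, or 0.309 with an estimated correlation and 0.09908 in the paired fit, and it did not pass under any other scaling, with the transcript set as covariate, in the larger set alone or without the library of lowest TMM factor (adjusted p = 0.05165 to 0.2039). Mast cell markers fell in 4 of 5 cases (4, with 1 higher, adjusted over the list alone), with TPSAB1 at -2.60 ± 0.59, and sweat gland markers in 5 of 11, with DCD at -4.57 ± 1.13. TPSAB1 and DCD did not pass with limma-voom (adjusted p = 0.07471 and 0.2911), nor DCD within the first layout (adjusted p = 0.07611). These lists did not pass (adjusted p = 0.07813 and 0.1766) but did in the paired fit (adjusted p = 0.04202 and 0.03803), where an estimated correlation ended both calls (adjusted p = 0.417 and 0.4371). Sebaceous markers fell in 2 of 9 cases and hair follicle markers rose in 2 and fell in 6 of 9 (adjusted p = 0.7257 and 0.1766). Of 3 red cell genes 2 rose, with HBB at 3.28 ± 1.10 (adjusted p = 0.2738 for the list; HBB did not pass within the first layout or with library size alone, adjusted p = 0.2433 and 0.0711), and none of 7 adipocyte markers changed (adjusted p = 0.964, median -0.23, mean 0.14).

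Leukocyte RNA could raise metabolic and keratinocyte lists in blister libraries. If it were the whole cause, the blister list scores extrapolated to the leukocyte score of nonblister libraries would fall to the nonblister level. The extrapolated score stayed above it by 2.08 (log2, bootstrap 95% interval 1.22 to 2.91) for hypoxia and glycolysis, 1.23 (1.01 to 1.49) for mTORC1-induced metabolic genes and 6.05 (5.18 to 6.91) for antimicrobial genes. Without the library of lowest TMM factor the differences were 2.13, 1.26 and 5.65. The slopes used were uncertain, because none of these 3 relations passed (Pearson r = 0.52, 0.2 and 0.421 in turn). Error in the leukocyte score would flatten them. The differences therefore argue against leukocyte RNA as the whole cause only if the relation is a straight line and that error is small. For wound keratins the difference was 9.01 (7.95 to 9.76), or 8.64 without the library of lowest TMM factor. Because their score fell as the leukocyte score rose, the extrapolation could only widen the observed gap, so this difference decides nothing. Leukocyte RNA as the whole cause needs a score that rises with the leukocyte score, and the wound keratin score did not, which argues against it. The extrapolation was run for these 4 lists and for no other, so not for the NF-kB, interferon and stress-response lists. Over the 9 blister libraries and 4 relations, the wound keratin score fell with the leukocyte score (Pearson r = -0.833, exact permutation p = 0.00502, adjusted p = 0.0201; Spearman rho = -0.717, exact permutation p = 0.0369, adjusted p = 0.147; r = -0.544 without the 2 farthest libraries), so the relation did not pass by rank, and the other 3 relations did not pass (lowest adjusted p = 0.295, by rank). No correlation was computed within the blister libraries of each layout (4 and 5). A share of the rise from leukocytes, the separation method and blistering itself stay open.

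The lower dermal markers could come from dilution of all resident cells by leukocyte RNA, or from dermis that the freeze-thaw separation left on nonblister epidermis. The dermal score minus the basal keratinocyte score was lower in blister libraries by a difference of -2.46 (log2, bootstrap 95% interval -3.09 to -1.81), which argues against dilution of all resident cells alike. Varying dermal carry-over would move fibroblast, endothelial and smooth muscle scores together over the 11 nonblister libraries. Pearson r was 0.79 for fibroblast and endothelial scores (permutation p = 0.00848, adjusted p = 0.0205 over 3 relations; Spearman rho = 0.727, permutation p = 0.0144, adjusted p = 0.0433; r = 0.781 without the 2 farthest libraries), 0.697 for endothelial and smooth muscle scores (permutation p = 0.0137, adjusted p = 0.0205; rho = 0.455, permutation p = 0.165, adjusted p = 0.247; r = 0.635 without the 2 farthest) and 0.321 for fibroblast and smooth muscle scores (permutation p = 0.326; rho = 0.218, permutation p = 0.521; r = 0.372 without the 2 farthest). Not all 3 relations passed, so the test left carry-over undecided. Every nonblister sample was freeze-thawed, so an effect of the separation method on dermal markers cannot be told apart from an effect of blistering. Within the 6 nonblister libraries of the first layout r was 0.901, 0.893 and 0.701 in the same order (exact permutation p = 0.0139, 0.0139 and 0.114; rho = 0.829, 0.829 and 0.6, exact permutation p = 0.0583, 0.0583 and 0.242). Without the 2 farthest libraries r was 0.742, 0.5 and -0.192. Correlations were not computed within the 5 nonblister libraries of the second layout.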
